A study of Bactrocera oleae with 2 samples.

How the data were processed

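The samples were 2 RNA-seq libraries from the esophageal bulb of adult female olive flies, *Bactrocera oleae*. The bulb is a diverticulum of the foregut, within the head, that houses the symbiotic bacterium Candidatus Erwinia dacicola. Per the labels, both samples were untreated wild type flies with the same batch date, each a pool of organs from 90 females aged 6 to 25 days, and they are called replicate 2 and replicate 3 here. Nothing in the labels says whether the pools came from separate rearings, so SDs measure only the spread between these samples, which may be technical. RNA was extracted with TRIzol, and stranded total RNA libraries were made after rRNA depletion (TruSeq, Ribo-Zero Plus), per the labels' protocols.

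The deposited values are raw read counts per gene, with no normalization, per the files' own summary rows, which are those HTSeq writes. The submitters' processing notes name fastp, HISAT2 and HTSeq. Their versions, the genome build and the strand setting of the counting are not given in the sources used here. Without a strand setting, overlapping and antisense genes cannot be told apart. Counts of near-identical paralogs, among them the 560 rRNA genes, are uncertain, as records aligned to several places have a summary row of their own. Each file lists 15962 genes and 5 summary rows. The summary rows were left out of library sizes and tests. They held 75.7% of records as not aligned in replicate 2 and 72.9% in replicate 3, 8.13% and 7.20% as aligned outside genes, 1.21% and 2.86% as low alignment quality, 1.67% and 3.52% as aligned to several places, and 0.0484% and 0.171% as ambiguous. Gene counts were 13.3% of records in each library.

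The files name genes by symbol or by a LOC identifier and give no product names. Biotypes were taken from the RefSeq gene table of assembly idBacOlea1 by symbol, which matched 15649 IDs. The other 313 are numbered tRNA copies. No coordinates are printed, because the build behind the counts is not named. Of 12391 protein-coding genes, 5883 have a symbol. The table gives genomic span and not exon length, so CPM was not divided by length, and a difference in CPM between genes also reflects their transcript lengths.

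CPM values were computed from the deposited counts by scaling the sum of gene counts of each library to 1000000. A gene was called detected with at least 10 counts in both libraries. A count of 0 allows up to 3 counts, which is 0.358 CPM in replicate 2 and 0.350 CPM in replicate 3. These floors cover counting error only, since PCR copies are not independent molecules. Agreement between libraries was described by Pearson's r and Spearman's rho of log2(CPM + 1), by a chi-square of the counts against sampling noise, and by the common biological coefficient of variation from edgeR 4.0.16 in R 4.3.3 with an intercept alone, with the median gene-wise estimate of DESeq2 1.42.0 as an alternative. With 1 group, edgeR's quasi-likelihood test has no contrast, so no test between conditions was made.

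The libraries were compared gene by gene with an exact two-sided conditional binomial test on the counts, with TMM-scaled library sizes and Benjamini-Hochberg adjustment over 9133 genes with at least 10 counts in either library. A gene was called at an adjusted p under 0.05. The test compares these libraries and not conditions. Its p-values cover counting error only, as reads are taken as independent, and do not estimate the spread between replicates. Log2 ratios are replicate 3 over replicate 2, with 0.5 added to each count. For each gene list, the median CPM of its detected members was placed as a percentile among 10000 random lists of the same size drawn from detected genes. A list was called high at a percentile of at least 95 in both libraries and low at 5 or less in both. Lists with under 3 detected members have no percentile. The median log2 ratio of a list was placed among 10000 random lists matched on mean expression in 50 bins, with every member with at least 10 counts in either library. These percentiles describe the libraries and are not tests across replicates. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

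The steps were tested on simulated data. Among 9133 simulated genes, the library test recovered 74.0% of 100 genes changed 2-fold and 92.0% of 100 changed 4-fold, and called 5 of 8933 unchanged genes. The simulated libraries held counting error only, as the test assumes. The real libraries had a chi-square per degree of freedom of 28.3, so these rates do not carry over to them. Among 8064 genes, 4.0% of 200 random lists of 20 genes passed the high threshold, and 89.0% of 100 lists raised 4-fold did. These lists used replicate 2 alone and were drawn from the same genes they were ranked against. The share of random lists passing was therefore set by the threshold and checks the code only.

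The tests, thresholds, alternatives and 29 of the 43 gene lists were chosen before the data were examined. Those lists had been written as patterns on symbols and product names. Since no product names were given, they were rewritten as lists of symbols after the gene names, but not the members' counts, had been seen. Members under LOC identifiers are therefore missed. Planned lists of lysozymes and of digestive serine proteases matched no symbol and were dropped. Lists added when the names were seen cover complement, opsonin and melanization genes, Osiris genes, lysosome and cathepsin genes, lipid and wax synthesis, neuropeptides, glia, foregut and midgut transcription factors, and a split of the planned chemosensory list into gustatory receptors, ionotropic and odorant receptors, and odorant binding proteins. The second eye list, the Hox list and the circadian clock list were added after exploring the data and before their own values were seen.

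Named genes follow a rule fixed with the design. They are the 25 protein-coding genes with the highest mean CPM, the 3 members with the highest mean CPM of each list, up to 6 for immune lists, and the 5 genes per direction with the largest log2 ratio among called genes with a mean CPM of at least 10. The rule had assumed product names and was applied to genes with a symbol, with 2 LOC identifiers named per kind. Of the genes this rule takes, 1 is not reported here. Alternatives changed the pseudocount, the detection threshold, the genes in the total, the random lists, the library scaling and the filter on low counts, and left out each replicate. Alternatives added after seeing the data used random lists of genes that have a symbol, left out rRNA genes, and left out the photoreceptor list with the genes over 2-fold different between the libraries. The Malpighian tubule data that the study set beside the bulb are not analysed here.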

Results

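RNA-seq of the esophageal bulb of adult female olive flies was used in the study to look for organ-specific gene expression beside published Malpighian tubule data, which are not analysed here. The series holds 1 group of 2 libraries, replicates 2 and 3, with 8383362 and 8570678 counts in genes. The files hold 63117341 and 64387091 records in all. Levels below are mean CPM ± SD of these libraries (n = 2).

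The most abundant transcripts with a symbol included an endocytic receptor, lipid elongation and sugar transport genes and subunits of the V-ATPase, the proton pump of acidified membranes. *mgl*, the megalin endocytic receptor, stood highest among genes with a symbol at 12579 ± 29.9 CPM, followed by *Msr-110* at 12041 ± 1621 CPM, *bond*, a fatty acid elongase, at 11059 ± 1422 CPM, and *hoe1* at 10699 ± 196 CPM. The sugar transporter *sut2* reached 7659 ± 133 CPM, *Vha16-1* 6518 ± 316 CPM, the glycosidase gene *tobi* 6357 ± 1905 CPM, *Drat* 6229 ± 9.74 CPM and *anchor* 5237 ± 740 CPM. *PGRP-LB*, an amidase that cleaves peptidoglycan and dampens Imd signalling, ranked 36 among all genes at 3265 ± 128 CPM.

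The rest of the 25 most abundant protein-coding genes with a symbol spanned several functions. *Vha55* (4880 ± 214 CPM) and *Vha26* (3564 ± 340 CPM) are further V-ATPase subunits. *Nep2*, a neprilysin peptidase, was at 4659 ± 138 CPM, *Ace*, acetylcholinesterase, at 4453 ± 266 CPM, *yin*, an oligopeptide transporter, at 4264 ± 353 CPM, and *FASN1*, a fatty acid synthase, at 3759 ± 360 CPM. The cytoskeletal genes *Msp300*, *shot* and *jbug* were at 4073 ± 191, 2710 ± 127 and 2616 ± 290 CPM. *eEF1alpha1*, a translation elongation factor, was at 3528 ± 374 CPM. *Gp150*, the furin protease gene *Fur2*, *mtgo*, *sas* and the ABC transporter gene *MRP* lay between 2378 ± 308 CPM, for *MRP*, and 2545 ± 2.94 CPM, for *Gp150*. Genes without a symbol were also abundant: LOC106618957 had the highest mean of any gene at 15702 ± 943 CPM, LOC106621440 reached 11548 ± 444 CPM, and 13 of the 25 most abundant genes carry a LOC identifier. The 10 most abundant genes held 11.1% ± 0.119 of gene counts and the 100 most abundant 36.3% ± 0.619. CPM was not divided by transcript length, so these levels do not rank molecules.

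**Figure D1:**
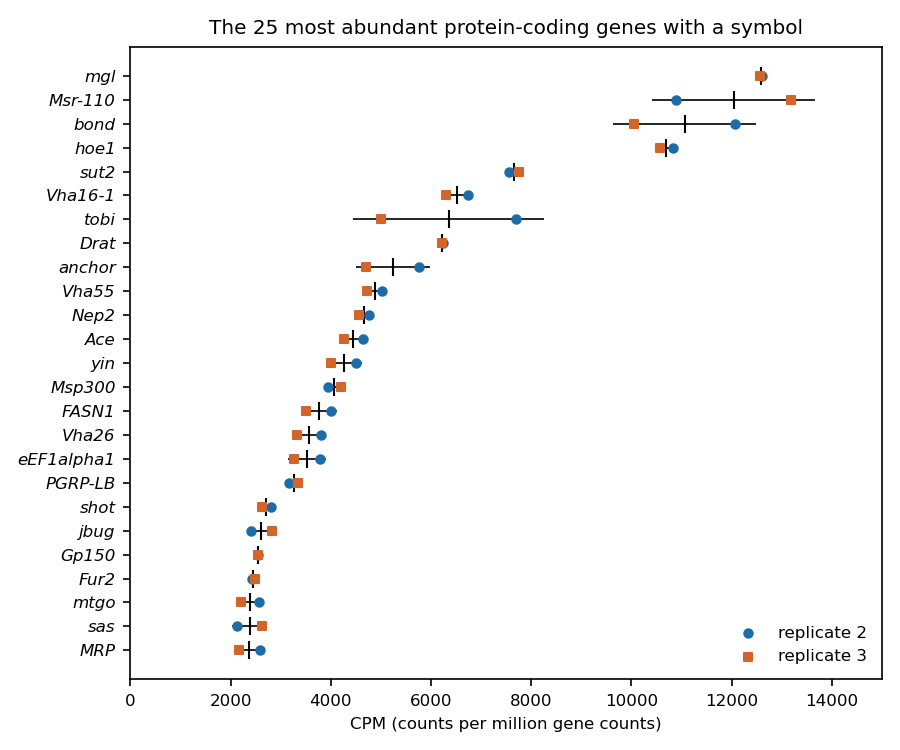
The 25 most abundant protein-coding genes with a symbol, with CPM on the horizontal axis. Blue circles are replicate 2, orange squares replicate 3, black ticks the mean and lines the SD (n = 2). *mgl* leads at 12579 CPM, and the libraries lie farthest apart at *tobi*, at 7704 and 5010 CPM.

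Among lists with at least 3 detected members, genes for acidification, transport and lipid synthesis formed those with the highest levels. The 15 detected of 17 V-ATPase genes had a median of 892 ± 79.6 CPM and held 2.23% ± 0.134 of gene counts. Of 15 genes of lipid and wax synthesis, a list added once names were seen, 12 were detected with a median of 279 ± 4.15 CPM, led by *bond*, *FASN1* and the acetyl-CoA carboxylase gene *ACC* (2123 ± 31.6 CPM). Among its other members, *Cyp4g1* had 2 and 16 counts and *FarO* 0 and 0, both named after their values were seen. The level of this list does not show that wax synthesis itself was high. All 5 sugar transporter genes were detected with a median of 270 ± 36.2 CPM, among them *Tret1-1*, a trehalose transporter, at 1039 ± 241 CPM and *sut1* at 269.9 ± 36.2 CPM. Of 14 ABC transporter genes, 12 were detected with a median of 162 ± 5.20 CPM, led by *MRP* and *Mdr49* (575 ± 141 CPM). The percentiles of these lists in replicates 2 and 3 were 100 and 100 for V-ATPase, 99.99 and 100 for lipid and wax synthesis, 99.6 and 99.5 for sugar transporters, and 99.9 and 99.9 for ABC transporters, and all 4 lists were called high. They were also high against random lists of genes with a symbol. The 10 amino acid transporter genes, with a median of 53.2 ± 0.754 CPM, were called neither high nor low (percentiles 84.7 and 85.2), with *slif* at 800.5 ± 167 CPM, *blot* at 529 ± 79.0 CPM and *Eaat1*, a glutamate transporter, at 529 ± 35.4 CPM.

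**Figure D2:**
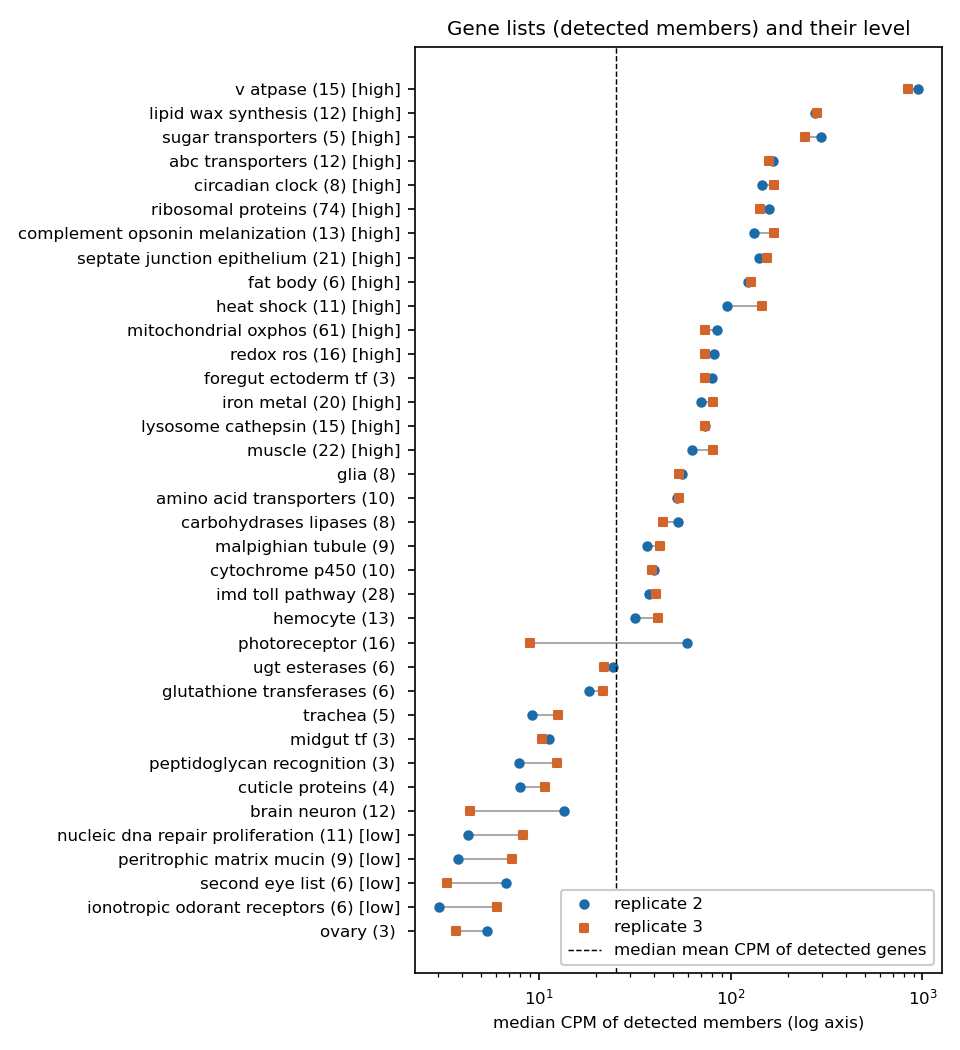
Median CPM of the detected members of each of 36 gene lists on a log axis, replicate 2 as blue circles and replicate 3 as orange squares, with the number of detected members and any high or low call beside the name. The dashed line is the median of mean CPM over detected genes. The V-ATPase list sits highest, at 892 CPM on average, and the photoreceptor list shows a wide gap between the libraries.

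Among the immune lists, *PGRP-LB* and *pirk* had the highest levels. Beside *PGRP-LB*, *pirk*, a negative regulator of Imd signalling, stood at 877 ± 148 CPM and the NF-kappaB factor *Rel* at 222 ± 16.1 CPM. In contrast, the peptidoglycan receptor genes *PGRP-LE* and *PGRP-SD* were at 9.19 ± 1.86 and 8.99 ± 4.95 CPM, *GNBP1* at 1.12 ± 0.268 CPM and *PGRP-SA* at 0.473 ± 0.174 CPM. *PGRP-LB* counts were 403 times those of *PGRP-LE* in replicate 2 and 320 times in replicate 3. Other Imd and Toll pathway genes were lower: *dnr1* at 155 ± 20.5 CPM, *Myd88* at 109 ± 3.29 CPM, the receptor gene *Tl* at 108 ± 5.32 CPM and *dl* at 107 ± 2.58 CPM. The one antimicrobial peptide list gene with a symbol, *edin*, had 0 and 6 counts. Effectors and peptidoglycan receptors under LOC identifiers were not examined, so low levels of the receptors named here do not speak for all of them. Peptidoglycan recognition (percentiles 16.4 and 26.8, 3 of 5 detected) and Imd and Toll pathway genes (82.4 and 85.6, 28 of 32 detected) were called neither. The list of complement, opsonin and melanization genes, added once names were seen, was called high (99.7 and 99.9, 13 of 15 detected). The list shares *Mcr* with the septate junction list and is broader than its name, as it also takes in the *Idgf* genes and *vir-1*. It was led by *Idgf6* at 661 ± 61.7 CPM, *Tep3*, a thioester protein gene, at 532 ± 61.5 CPM, *Idgf4* at 377 ± 97.5 CPM, *vir-1* at 367 ± 70.1 CPM, *Mcr* at 239.7 ± 2.76 CPM and *Sp7*, a serine protease gene, at 168 ± 1.37 CPM. Of 13 tested genes of this list, 8 were called higher in replicate 3 and 1 in replicate 2, with a median log2 ratio of 0.42 (matched percentile 99.96). The hemocyte list, which shares the prophenoloxidase genes *PPO1* (1.27) and *PPO2* (1.96) with it, had a median of 0.93. Both genes are named after their values were seen.

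The septate junction and epithelial list was called high, the peritrophic matrix, mucin and chitin list low, and the cuticle protein list neither. Septate junction and epithelial genes, 21 of 24 detected, had a median of 148 ± 10.4 CPM, with *scrib* at 743 ± 19.8 CPM, *Lac* at 388 ± 17.1 CPM and *Gli* at 320.3 ± 8.09 CPM (percentiles 99.98 and 100, called high). Its undetected members, named after their values were seen, were *Ssk* (6 and 2 counts), *Tsp2A* (0 and 0) and *hoka* (0 and 0). Peritrophic matrix, mucin and chitin genes, 9 of 28 detected, had a median of 5.53 ± 2.42 CPM and were called low (0.335 and 3.97), with the chitin deacetylase genes *serp* at 52.2 ± 24.0 CPM and *verm* at 18.8 ± 6.30 CPM and the chitinase gene *Cht11* at 36.3 ± 0.234 CPM. With detection set at 50 counts this low call ended (mean percentile 21.8). Of 58 cuticle protein genes, 33 had no count in either library and 4 were detected (percentile 8.78 in replicate 2 and higher in replicate 3, called neither), with *Cpr57A* at 26.7 ± 8.34 CPM and *Cpr60D* at 13.4 ± 3.21 CPM. Of 23 Osiris genes, 0 were detected and 20 had no count in either library. *Osi6* had 0 and 6 counts, *Osi24* 4 and 1, and *Osi17* 0 and 2.

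Redox, metal and lysosome genes were called high, but these calls rested on the choice of random lists. *Prx2*, a peroxiredoxin, was at 1292 ± 118 CPM, *Sod1*, superoxide dismutase, at 794 ± 69.7 CPM and the antioxidant transcription factor gene *cnc* at 507 ± 37.8 CPM, while *Duox* and *Nox*, genes of oxidases that make reactive oxygen species, were at 0.703 ± 0.656 and 1.31 ± 1.19 CPM and are named after their values were seen. The ferritin subunit genes *Fer2LCH* and *Fer1HCH* reached 1125 ± 191 and 1027 ± 265 CPM and *Tsf1*, transferrin, 420.2 ± 23.2 CPM. *Sap-r*, *Lamp1* and the cathepsin gene *CtsL1* reached 1908 ± 84.3, 1796 ± 160 and 1291 ± 169.7 CPM. The percentiles were 98.4 and 97.3 for redox genes (16 of 19 detected), 98.3 and 99.2 for iron and metal genes (20 of 24), and 97.3 and 97.3 for lysosome and cathepsin genes (15 of 19), a list added once names were seen. Against random lists of genes with a symbol, these were 94.6 and 92.5, 92.2 and 96.2, and 90.4 and 91.4, which ended each call. Setting detection at 50 counts also ended the calls of redox (mean percentile 89.7) and of iron and metal genes (94.6).

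The carbohydrase and lipase list and the detoxification lists were called neither high nor low. *tobi* led the carbohydrase and lipase list, whose other leading members were *Treh*, trehalase, at 369.5 ± 29.2 CPM and the lipase gene *bmm* at 107 ± 15.8 CPM (percentiles 82.0 and 74.8, 8 of 13 detected). Among cytochrome P450 genes, *Cyp313b1* was at 585 ± 177 CPM, *Cyp6d4* at 241 ± 9.86 CPM and *Cyp6u1* at 72.4 ± 0.631 CPM (73.6 and 71.2, 10 of 25). *GstE12* was at 125 ± 18.05 CPM, *GstT3* at 43.5 ± 9.16 CPM and *GstE11* at 29.4 ± 7.97 CPM among glutathione transferase genes (31.9 and 38.6, 6 of 9). The juvenile hormone epoxide hydrolase gene *Jheh2* was at 198.5 ± 55.5 CPM, *Ugt316A1* at 97.2 ± 3.15 CPM and *Ugt317A1* at 32.3 ± 3.59 CPM in the list of UDP-glycosyltransferases, esterases and epoxide hydrolases (44.6 and 39.04, 6 of 10).

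Housekeeping lists were placed in the same way. A percentile depends on the size of a list as well as its level, so it does not rank lists of unlike size. Sugar transporters, with 5 genes and a median of 270 CPM, had lower percentiles than oxidative phosphorylation genes, with 61 and 79.4 CPM. Ribosomal protein genes (74 of 75 detected, percentiles 100 and 100) had a median of 151 ± 11.7 CPM, with *RpL4* at 552 ± 48.8 CPM, *RpL3* at 523 ± 29.6 CPM and *RpLP0* at 472 ± 78.9 CPM. Nuclear genes of oxidative phosphorylation (61 of 65, 100 and 99.99) had a median of 79.4 ± 8.33 CPM, with *blw* at 1357 ± 238 CPM, *ATPsynC* at 679 ± 100.9 CPM and *SdhA* at 474 ± 38.3 CPM. Heat shock genes (11 of 12, 98.1 and 99.8) were also high, with *Hsc70-4* at 2196 ± 19.6 CPM, *Hsp83* at 974 ± 81.7 CPM and *Hsc70-3* at 567 ± 101.03 CPM. Replication and cell cycle genes (11 of 16) were called low (0.225 and 3.96), with *Top2* at 102 ± 5.69 CPM, *RnrL* at 57.8 ± 1.65 CPM and *aurB* at 26.1 ± 1.07 CPM. The heat shock call ended against genes with a symbol (94.4 and 99.3). The replication call ended with detection at 50 counts (mean percentile 25.2), with random lists of genes with any count (14.3), and without the photoreceptor list and the genes over 2-fold different (7.42).

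Markers of other tissues that a dissection from the head could carry were measured in the same way. Muscle genes, 22 of 25 detected, were called high (97.55 and 99.4), with *Zasp52* at 1062 ± 240.2 CPM, *bt* at 650.5 ± 34.5 CPM and the myosin heavy chain gene *Mhc* at 428 ± 44.4 CPM. Fat body genes, 6 of 7 detected, were called high (96.5 and 96.8), with the lipophorin gene *apolpp* at 534 ± 136 CPM, *Lsp2* at 327 ± 67.4 CPM and *Apoltp* at 164 ± 45.2 CPM. Both calls ended against genes with a symbol, at 89.0 and 97.2 for muscle and 92.8 and 93.7 for fat body. The fat body call also ended with detection at 50 counts (mean percentile 94.8) and with random lists of genes with any count (97.1, with 1 library under 95). Hemocyte genes (64.7 and 78.7, 13 of 17 detected), led by *atilla* at 533 ± 137 CPM, *crq* at 136 ± 12.6 CPM and *Hml* at 133 ± 18.1 CPM, were called neither. Trachea genes (15.6 and 22.9, 5 of 7) were also called neither, with *pio* at 342 ± 84.8 CPM, *uif* at 76.2 ± 18.2 CPM and the FGF gene *bnl* at 9.67 ± 0.683 CPM.

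Malpighian tubule genes were called neither (69.7 and 76.2, 9 of 16 detected), with the chloride channel gene *Best2* at 1605 ± 222 CPM, *Drip*, an aquaporin, at 332 ± 169.8 CPM and the potassium channel gene *Irk1* at 185 ± 10.6 CPM. In the ovary list, 3 of 17 genes were detected, with *vas* at 13.3 ± 2.63 CPM, *bam* at 4.55 ± 1.16 CPM and *nanos* at 2.42 ± 0.0456 CPM (percentiles 9.49 and 4.40, low in replicate 3 alone, but 4.06 and 1.78 against genes with a symbol, low in both). Of the salivary gland list, *fkh*, a forkhead transcription factor gene, was detected at 861 ± 7.14 CPM, while *sage* had 0 and 5 counts and *Sgs5bis* 0 and 4. Brain and neuron genes, 12 of 23 detected, lay at percentiles of 15.7 and 0.115 and were called low in replicate 3 alone but in both libraries against genes with a symbol (4.505 and 0), with *elav* at 539 ± 90.2 CPM, *unc-13* at 142 ± 43.3 CPM and *Syx1A* at 133 ± 1.92 CPM. Photoreceptor genes, 16 of 21 detected, lay at 94.0 in replicate 2 and 2.64 in replicate 3, with *rdgA* at 395 ± 12.5 CPM, the rhodopsin gene *ninaE* at 354 ± 400 CPM and *rdgB* at 166 ± 17.5 CPM.

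The libraries gave close levels for most genes. Of 8064 genes detected in both, 79.8% lay within 1.5-fold and 91.9% within 2-fold, and the median coefficient of variation was 12.4%. Across 11608 genes with a count in either library, Pearson's r of log2(CPM + 1) was 0.963 and Spearman's rho 0.944, and genes are not independent replicates. The chi-square per degree of freedom was 28.3, so the files differed by more than sampling noise and are not copies of each other, which does not show that the pools were independent. The common biological coefficient of variation from edgeR was 41.3%, and 27.98% without rRNA genes, while the median gene-wise estimate of DESeq2 was 10.2%. The detected genes were 50.5% of those listed and included 7587 protein-coding genes. A further 463 genes reached 10 counts in replicate 2 alone and 606 in replicate 3 alone, 145 of the latter rRNA genes, and 4354 had no count in either.

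**Figure D3:**
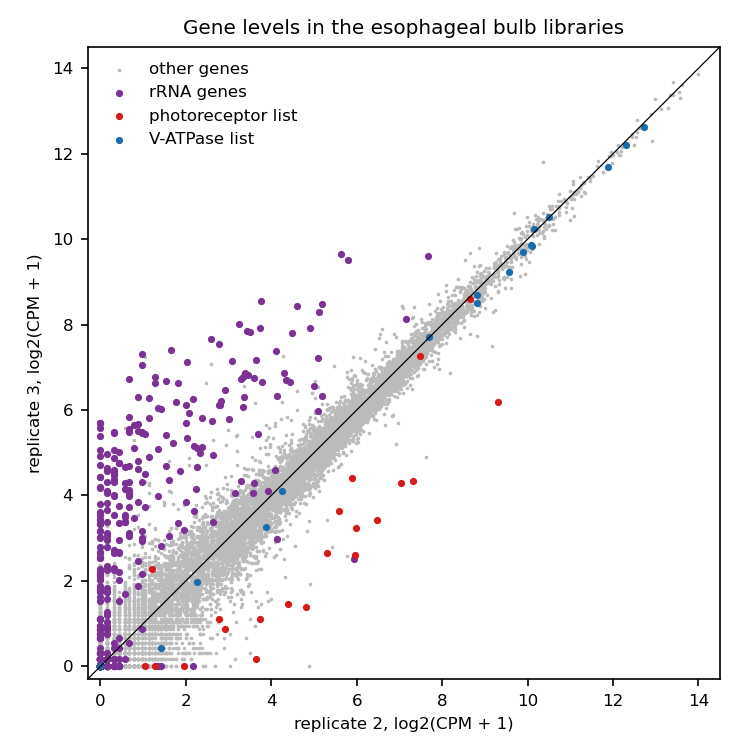
Gene levels as log2(CPM + 1) in replicate 2 (horizontal) and replicate 3 (vertical), over genes with a count in either library, with the line of equality. Grey points are other genes, purple rRNA genes, red the photoreceptor list and blue the V-ATPase list. Of 237 rRNA genes tested, 232 had a log2 ratio above 0, and of 20 photoreceptor genes tested, 18 were called higher in replicate 2.

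Photoreceptor genes were the list with the lowest ratio between the libraries. *ninaE* was at 637 CPM in replicate 2 and 71.5 CPM in replicate 3, and the rhodopsin gene *Rh6* was 15.8-fold, the arrestin gene *Arr1* 11.6-fold, the kinase gene *inaC* 10.9-fold, *Ggamma30A* 10.4-fold and the histidine decarboxylase gene *Hdc* 9.95-fold higher in replicate 2. The median log2 ratio of the photoreceptor list was -2.96 (matched percentile 0), with 18 of 20 genes called higher in replicate 2 and 1, *Rh2* (1.53), named after its values were seen, called higher in replicate 3, and 19 called when adjusted over the list alone. *rdgA* was not called, at a log2 ratio of -0.05. Brain and neuron genes were lower with them, with a median of -0.82 (matched percentile 0.01), 11 of 16 called higher in replicate 2, 0 in replicate 3, and 11 called when adjusted over the list alone.

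Smaller shifts towards replicate 2 were seen in lists of high level. The median log2 ratios were -0.17 for V-ATPase genes (11 of 16 called higher in replicate 2, 1 in replicate 3, 12 adjusted over the list alone), -0.23 for oxidative phosphorylation genes (35 and 1 of 61, 39 adjusted over the list alone), -0.11 for ribosomal protein genes (35 and 12 of 74, 51 adjusted over the list alone) and -0.26 for lipid and wax synthesis genes (8 and 1 of 14). Their matched percentiles were 1.02, 0, 0.10 and 0.18. Redox genes (-0.16, percentile 2.96) and the carbohydrase and lipase list (-0.26, percentile 3.36) also lay low.

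The hemocyte, trachea, muscle and chitin matrix lists had median log2 ratios above 0. Hemocyte genes had a median log2 ratio of 0.93 (matched percentile 100), with 11 of 16 called higher in replicate 3, 3 called higher in replicate 2, and 14 called when adjusted over the list alone. The 3 were *atilla* (-0.51), *crq* (-0.17) and *drpr* (-0.23), among the most abundant of the list and with *drpr* named after its values were seen, and the list held 0.121% of gene counts in replicate 2 and 0.112% in replicate 3. The medians were 0.76 for trachea (99.3, 5 of 6 called higher, 5 adjusted over the list alone), 0.23 for muscle (99.8, 12 of 23 called higher and 1 lower, 14 adjusted over the list alone) and 0.71 for peritrophic matrix, mucin and chitin genes (99.3, 6 of 15 called higher, 6 adjusted over the list alone). Sugar transporters (0.25, percentile 95.2) and Malpighian tubule genes (0.28, percentile 95.4) also lay high, and cuticle genes (0.67) were at 94.99. With few genes tested, neuropeptide genes had a median of 2.01 (percentile 99.45, 3 of 5 called higher and 2 lower). Odorant binding protein genes had a median of 1.10 (percentile 96.7, 2 of 3 called higher). Single genes higher in replicate 3 were the cuticle gene *Cpr49Ah* at 0.477 and 46.6 CPM, the chitinase gene *Cht10* (8.81-fold), *Lk*, the leucokinin neuropeptide gene (4.04-fold), *bnb* (3.78-fold) and *Esyt2* (3.26-fold). Summed rRNA counts were 11179 and 110132, 0.133% and 1.28% of gene counts, so 9.76-fold higher in replicate 3 after scaling. Records aligned to several places, which have their own summary row, were 1.67% and 3.52% of all records. The summed rRNA counts therefore do not measure all rRNA in the libraries.

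**Figure D4:**
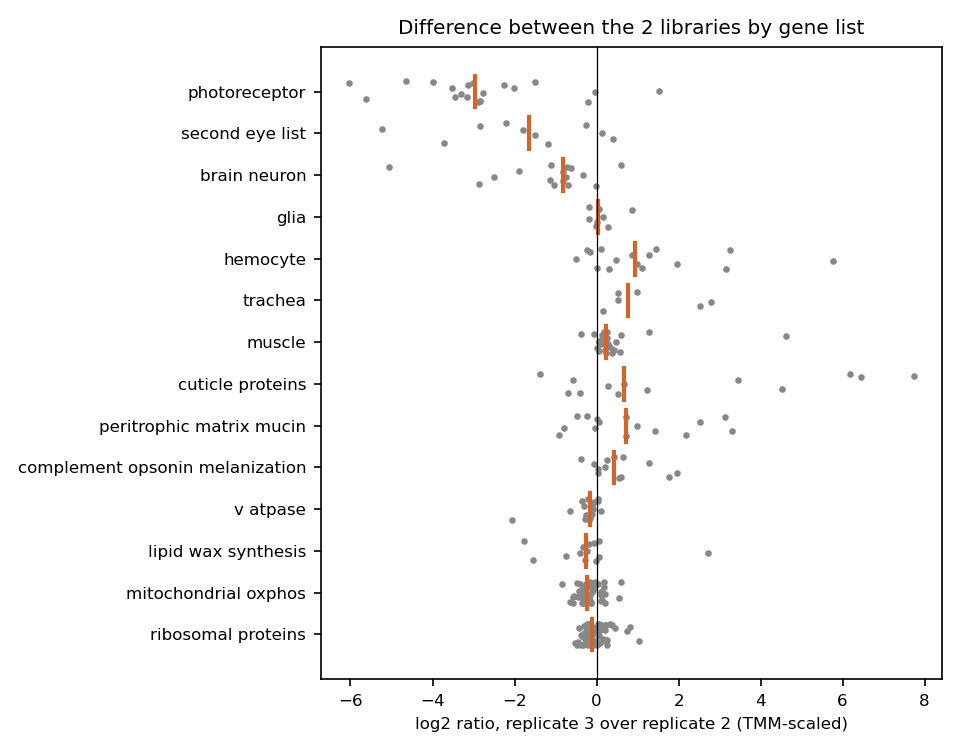
Log2 ratio of replicate 3 over replicate 2 (horizontal) for each tested member of 14 gene lists (grey points), with the list's median as an orange bar. Photoreceptor genes centre on -2.96 and hemocyte genes on 0.93.

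Over all genes, 4052 of 9133 were called between the libraries, 2110 higher in replicate 3 and 1942 higher in replicate 2, by the exact conditional binomial test with Benjamini-Hochberg adjustment. Of these, 1309 differed over 2-fold. Among 5710 genes with a mean CPM of at least 10, 259 were called and over 2-fold different, 211 higher in replicate 3, of which 116 were rRNA genes, and 48 higher in replicate 2. Among genes without a symbol, LOC106623817 had 0 counts in replicate 2 and 448 in replicate 3, at least 148-fold higher against a floor of 3 counts per library, and the rRNA gene LOC138858770 had 0 and 438, at least 145-fold higher. LOC118681711 had 237 and 0, at least 79.7-fold higher in replicate 2, and the rRNA gene LOC138858435 had 503 and 40, 12.5-fold higher in replicate 2. Keeping only genes with at least 50 counts in both libraries left 154 genes over 2-fold different. The test compares these libraries and says nothing of a condition. It takes reads as independent and covers counting error only, and with a chi-square per degree of freedom of 28.3 these counts of calls do not show differences beyond the spread between replicate pools.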

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

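The tests of scaling, of small non-coding RNAs and of the unaligned reads were chosen after the results were seen. The test of the second eye list was fixed before its values were seen.

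Most of each library lay outside the gene counts. In replicate 2, 75.7% of records were not aligned, and in replicate 3, 72.9%, for a mean of 74.3%. Of the aligned records, 33.4% and 26.6% lay outside annotated genes. RNA of other organisms in the bulb, such as its symbiont, may be among the unaligned reads, but the count tables hold no sequence, so this cannot be told apart from rRNA that does not match the genome or from short or poor reads.

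Photoreceptor genes were higher in replicate 2, with a median log2 ratio of -2.96 and an SD of 1.79 over 20 genes. In unscaled counts, the median log2 ratio of the list lay at -2.95 relative to that of all detected genes (0.01), beyond the SD. A scaling factor moves the log2 ratios of all genes alike, so it cannot set a list apart from the others. For the same reason this test of scaling could not have come out otherwise and adds no support. Eye tissue carried over with the bulbs of replicate 2 may explain the photoreceptor shift: the second eye list, which shares no gene with the first, had a median of -1.65 over 10 genes, at matched percentile 0, with 7 called higher in replicate 2 and 0 in replicate 3. *ninaE* stood at 637 and 71.5 CPM, while *rdgA*, *rdgB*, *santa-maria*, *pinta* and *laza* had log2 ratios of -0.05, -0.20, 0.13, 0.41 and -0.25. *rdgA* (386 CPM) and *rdgB* (153 CPM) stood above *ninaE* in replicate 3. How far added eye tissue would move *rdgA* and *rdgB* depends on their levels in the eye, which were not measured. Their ratios therefore do not decide for or against carry-over. Why *santa-maria*, *pinta* and *laza* did not shift was not tested. The rhodopsin gene *Rh2*, with 11 and 33 counts, was called higher in replicate 3 (1.53). Eye tissue carried over in replicate 2 alone would not raise it in replicate 3. Whether other tissue was carried over in replicate 3 was not tested. Both libraries belong to 1 group, so no biological explanation was tested.

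rRNA genes were higher in replicate 3, in 232 of 237 tested (97.9%). The rRNA gene LOC138858435 went the other way, with 503 counts in replicate 2 and 40 in replicate 3. A better recovery of all small non-coding RNAs is argued against by the summed snoRNA, snRNA and tRNA counts, whose log2 ratio was 0.39 against 3.29 for rRNA. Less complete rRNA depletion of replicate 3 was not tested and may be the source. No biological explanation was tested.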

How the results depend on the processing

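Random lists of genes with a symbol, the analyses without rRNA genes, and those without the photoreceptor list and genes over 2-fold different were chosen after seeing the data. Pearson's r was 0.956 with a pseudocount of 0.5, 0.974 with 5, 0.964 over genes detected in both libraries and 0.975 over all genes listed. Spearman's rho was 0.959 and 0.949 over those gene sets. The biological coefficient of variation was 10.2% as DESeq2's median gene-wise estimate and 27.98% without rRNA genes. The 10 most abundant genes held 11.4% of protein-coding counts. Of 36 lists, 15 were high, falling to 9 against genes with a symbol. The 4 low lists became 7 against genes with any count, where lists with few detected members also enter, 6 against genes with a symbol, 0 with detection at 50 counts, 2 without the photoreceptor list and genes over 2-fold different, and from 4 to 7 with either replicate left out, where replicate 3 alone adds the brain and neuron, photoreceptor and ovary lists. Genes called and over 2-fold different fell from 1309 to 154 with at least 50 counts in both libraries, a filter that also drops genes because they are low in either library. The cause of the other changes was not tested. Against genes with any count, Imd and Toll (mean percentile 99.1), amino acid transporter (96.7) and glia lists (95.4) became high, and cuticle (0.0575) and ovary lists (0.353) low. All members of these lists have a symbol. Against genes with a symbol, Imd and Toll genes lay at 50.8 and 60.7 in replicates 2 and 3 and were not high. Amino acid transporters lay at 68.7 and 70.9 and glia at 69.7 and 69.05, also not high. Cuticle genes lay at 3.87 and 7.32, low in replicate 2 alone. The photoreceptor median log2 ratio lay between -2.77 and -3.02 under every alternative run, and 4042 to 4094 genes were called with the other scalings, which moved log2 ratios by 0.00 and -0.02. Without the 10 most abundant genes in the total, 73 of 165 named levels moved by more than 1 SD and 92 did not. Division by exon length was not run, as the gene table gives genomic span. No paired analysis was possible because there is 1 group. Depth limits statements on genes under 10 counts.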

Other observations

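The circadian clock, Hox and second eye lists were chosen after the data had been explored and before their own values were seen, and the other lists here were written once gene names were seen.

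Circadian clock genes were high in both libraries. All 8 were detected, with a median of 157 ± 16.03 CPM (SD, n = 2; percentiles 99.2 and 99.6), led by *Pdp1*, a PAR-domain transcription factor gene, at 1615 ± 137 CPM, *tim*, timeless, at 1161 ± 28.7 CPM and *cry*, cryptochrome, at 348 ± 50.4 CPM. Of transcription factor genes, *fkh* was at 861 ± 7.14 CPM, *Hnf4* at 324 ± 21.4 CPM, *bowl* at 77.1 ± 4.54 CPM, *pdm3* at 10.9 ± 0.67 CPM, *Sox21b* at 5.73 ± 6.92 CPM and *cad* at 1.30 ± 0.187 CPM. The foregut list (83.9 and 82.0, 3 of 10 detected) and the midgut list (25.7 and 21.85, 3 of 5) were called neither high nor low. Of 7 Hox genes, 0 were detected in both libraries, with *Antp* at 0 and 11 counts, *Ubx* at 0 and 6 and *abd-A* at 0 and 2.

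Signalling and sensory genes were few but included abundant members. Of 28 neuropeptide genes, 2 were detected: *ITP*, an ion transport peptide gene, at 881 ± 241 CPM and *Lk* at 44.7 ± 37.9 CPM, while *CCHa2* had 0 and 32 counts. The odorant receptor gene *Or46a* was at 111 ± 8.16 CPM, against 9.01 ± 9.702 CPM for *Ir75d* and 6.86 ± 2.44 CPM for *Ir31a*, and the list of ionotropic and odorant receptors was called low (0.275 and 3.20, 6 of 36 detected). Of 26 gustatory receptor genes, 1 was detected, *Gr32a* at 5.09 ± 2.75 CPM, with *Gr47b* and *Gr64a* each at 8 and 18 counts. Of 15 odorant binding protein genes, 2 were detected, *Obp19d* at 11.8 ± 2.27 CPM and *Obp99b* at 5.99 ± 3.08 CPM, and *Obp44a* had 1 and 25 counts. Glia genes (83.9 and 82.4, 8 of 9 detected) were called neither, with *Eaat1*, *Gs2*, glutamine synthetase, at 382 ± 153 CPM and *nrv2* at 200.5 ± 24.7 CPM. The second eye list was called low (4.635 and 0.295, 6 of 12 detected), with *santa-maria* at 38.0 ± 2.16 CPM, *PIP82* at 8.39 ± 9.06 CPM and *inaF-D* at 5.81 ± 3.26 CPM, a call that ended with random lists of genes with any count (mean percentile 10.7) and without the photoreceptor list and genes over 2-fold different (6.22).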
